A study of Mus musculus with 19 samples.

How the data were processed

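Total RNA of sorted mouse endothelial cells was extracted with a column kit for small samples, amplified and converted to labelled single-stranded cDNA with whole-transcript kits, and hybridised to Affymetrix whole-transcript arrays, per the labels. The deposited values of the 19 arrays are log2 signals that were summarised with RMA and handled in Partek per the submitters' processing notes, which give no versions. RMA corrects background, quantile-normalises arrays and summarises the probes of a probe set, and it compresses large folds. The values had been centred for each probe set, since they ran from -4.092 to 6.128 and 54.47% of probe sets held an exact 0. The median over these 19 arrays was exactly 0 in 8.01% of probe sets, so the baseline was not that median, and the sources used here do not state it. The direction follows from the log2 scale, while the absolute level, signal over background and detection of a gene stay unknown, and no bound at background could be set. Arrays have no read depth, and their number sets the precision.

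Of 28856 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 5446 were unnamed here. Through the Entrez identifier 21698 were matched to a gene table of assembly GRCm38.p6, which changed 0 symbols. Probe sets with several symbols were not named, and the mean over probe sets was taken for the 999 genes with more than 1, which left 19938 genes. The planned choice was the probe set with the highest mean, but on centred values this does not pick the brightest, so it was run as an alternative. None of the 87 genes named as largest or as fixed markers had more than 1 probe set. Ccl21a lay only on shared probe sets and was not analysed here, and some members of the gene lists are not reported here. Coordinates were not used.

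Groups were taken from the sample titles. A linear model with 1 mean for each of 7 groups was fitted to all 19 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 12 residual degrees of freedom, a prior of 4.62 degrees of freedom and a prior SD of 0.145. Contrasts gave HEC against capillary cells in each tissue and as the mean of 3 tissues, tissue differences within each cell type, 3 interactions and the mesenteric gates, with the mean of both gates as mesenteric HEC. P-values were two-sided and adjusted by Benjamini-Hochberg over the 19938 genes for each contrast, with a threshold of 0.05. Differences are given on the log2 scale with the SE of the model. No batch, slide or scan date was used, as the labels give none. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

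The contrasts, the rule for named genes, the gene lists and a first set of alternatives were fixed before the data were examined. Named genes were the 10 highest and 10 lowest differences in HEC against capillary cells (mean of tissues) and in Peyer's patch against peripheral HEC, and the 5 highest and 5 lowest elsewhere, among genes past the threshold with an absolute log2 difference of at least 1 and, outside interactions, groups that did not overlap. Predicted genes, receptor families used as background, small RNAs and antigen receptor segments were left out. To these came up to 4 of the largest called members of each list described and a set of fixed endothelial and homing genes. There were 39 gene lists, with 635 of 681 genes measured. Lists were tested with camera at an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, with an estimated correlation and the self-contained test fry as alternatives.

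The first alternatives were the replicate number as a block, each array left out in turn, the probe set with the highest mean, quantile normalization again, centring each array on its median, array quality weights, and a fit of only the compared groups. A filter on dim genes and an intensity trend in the prior need signal levels and were not run. A filter on the range over arrays (8736 genes kept, range over 0.770, the 95th percentile of 1196 receptor genes used as background), a robust prior, the most variable probe set, a fit without peripheral capillary arrays 1 and 2, a fit without array 1 of both peripheral groups, and mesenteric HEC arrays paired by correlation were added after seeing the data. Both tests were checked on simulated data for Peyer's patch against peripheral HEC over 19938 genes. Of 100 genes set to a log2 change of 1, 94% were recovered, and of 100 set to 2, 100%, with 8 unchanged genes among 202 called. In the same data, mesenteric against peripheral capillary cells, which held 0 changed genes, gave 0 calls. Camera found the 1 shifted list and called 0 of the others in 21. The simulated genes varied independently, so this does not check camera on lists whose members correlate, such as intestinal epithelial markers (estimated correlation 0.465). Each gene had the same spread on all arrays, so the wider spread of some Peyer's patch HEC arrays was not simulated.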

Results

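RNA from sorted endothelial cells of 3 lymphoid tissues of BALB/c mice, an inbred strain, was measured on 19 single-channel expression arrays. Per the labels each sample mixed male and female adults equally, aged 6 to 8 weeks. High endothelial cells (HEC) line the venules through which lymphocytes leave the blood, and capillary cells were sorted from the same kinds of tissue. Peripheral lymph nodes gave 4 HEC and 3 capillary arrays, and Peyer's patches, the lymphoid follicles of the gut wall, gave 3 of each. Mesenteric lymph nodes, which drain the gut, gave 2 capillary arrays and 4 HEC arrays, of which 2 were sorted as positive for MAdCAM1 and PNAd and 2 as positive for MAdCAM1. MAdCAM1 is the mucosal vascular addressin and PNAd the sulfated sugar epitope bound by L-selectin. The title of the series sets capillary and high endothelium side by side with a view to lymphocyte homing. Values were log2 signals centred for each probe set, so they give differences between arrays and no level of one gene against another. The number of arrays limits their precision, and the labels do not say that replicates came from separate animals or sorts, so p-values measure only the spread between these samples, which may be technical. The SD over genes of the difference between 2 replicate arrays was 0.450 for arrays 2 and 3 of Peyer's patch HEC and 0.196 to 0.312 for all other pairs within a group.

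High endothelium was first set against capillary endothelium as the mean of the 3 tissues (11 HEC and 8 capillary arrays). Genes of lymphocyte capture were among those that stood highest in HEC. Madcam1 was higher by 4.95 ± 0.13 log2 (± SE, adjusted p = 8.79e-15) and Glycam1, a secreted mucin that carries L-selectin ligands, by 4.41 ± 0.29 (adjusted p = 1.34e-09). MAdCAM1 was a gating antigen of the mesenteric HEC sorts, so Madcam1 is no finding there. The double-positive mesenteric HEC were also gated on PNAd, so genes of L-selectin ligand synthesis may partly restate the sort there. The labels do not give the gates of the capillary sorts or of the peripheral and Peyer's patch HEC sorts. Of 14 measured genes of L-selectin ligand synthesis, 9 were higher and 1 was lower in HEC over all genes tested, and 9 higher and 1 lower adjusted over the list alone. The camera test of the list gave an adjusted p = 3.56e-06, and an adjusted p = 0.0744 with an estimated correlation. Its largest members were Gcnt1, which builds the core branch of mucin sugars (4.02 ± 0.13), the sulfotransferase Chst4 (3.99 ± 0.21) and the fucosyltransferase Fut7 (3.00 ± 0.10). The sulfotransferase Chst2 (1.13 ± 0.08) and B3gnt3, which extends core sugars (0.83 ± 0.07), were higher by less. Of 16 measured leukocyte adhesion molecules 7 were higher and 3 lower (8 higher and 3 lower adjusted over the list alone), with a camera adjusted p = 0.0203 and an adjusted p = 0.37 with an estimated correlation, and Sele, the endothelial selectin, was higher by 2.11 ± 0.16. Cd34, another carrier of L-selectin ligands, differed by -0.15 ± 0.08 and did not pass (adjusted p = 0.193).

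Chemokine receptors divided between the cell types. The atypical receptors, which bind chemokines without classical signalling, included Ackr2 (3.10 ± 0.11) and Ackr1 (3.07 ± 0.11), both higher in HEC, while Cxcr4 (-2.54 ± 0.13), the receptor of Cxcl12, and Ackr3 (-1.77 ± 0.08), its scavenger, were lower. In all, 2 of the 7 measured members of that list were higher and 4 lower, 2 higher and 4 lower adjusted over the list alone, and the camera test did not pass (adjusted p = 0.537). The list's median was -0.19 and its mean 0.15. Among 15 measured chemokines 4 were higher and 3 lower (5 higher and 3 lower adjusted over the list alone), and the list did not pass (adjusted p = 0.853, median 0.07, mean -0.17). Cxcl12 (-3.84 ± 0.08) and the membrane-bound Cx3cl1 (-2.96 ± 0.10) were lower in HEC, and the interferon-inducible Cxcl10 was higher (1.56 ± 0.09). The vein-fate transcription factor Nr2f2 was higher by 1.97 ± 0.09 and Lrg1, a venule-enriched secreted glycoprotein, by 2.83 ± 0.08. Of 9 measured venous genes 5 were higher and 3 lower (5 higher and 3 lower adjusted over the list alone). The camera test gave an adjusted p = 0.0424, and an adjusted p = 0.215 with an estimated correlation. Lyve1, a hyaluronan receptor best known from lymphatic vessels, was higher in HEC by 3.19 ± 0.22 and the related scavenger receptor Stab2 by 1.78 ± 0.09, while Itih5 (-2.30 ± 0.10) and the lymphatic receptor Flt4 (-1.49 ± 0.08) were lower. That list of 11 lymphatic markers had 3 higher and 5 lower (3 higher and 5 lower adjusted over the list alone) and did not pass camera (adjusted p = 0.219).

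**Figure D1:**
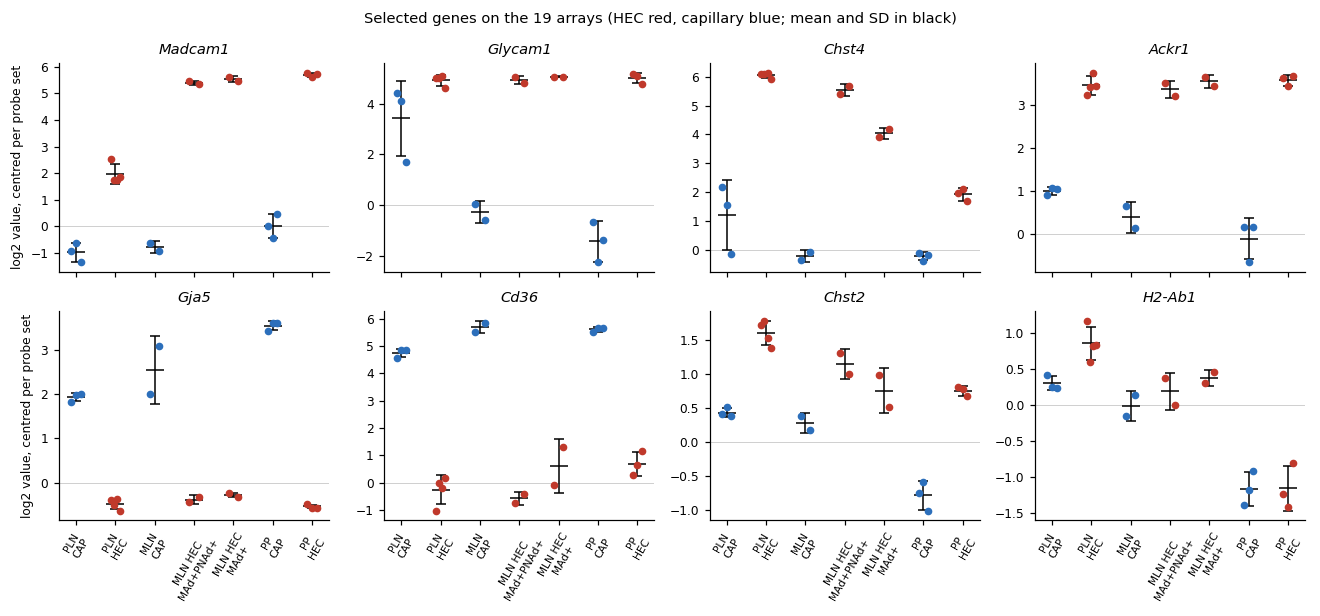
Deposited log2 values, centred per probe set, of 8 genes on the 19 arrays by group, with HEC arrays in red, capillary arrays in blue and the mean and SD of each group in black. PLN, MLN and PP stand for peripheral and mesenteric lymph nodes and Peyer's patches, CAP for capillary, and MAd for MAdCAM1. Glycam1 lay at 4.42, 4.11 and 1.70 on the peripheral capillary arrays, and Chst4 was lower in Peyer's patch HEC than in the other HEC groups.

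Genes of the secretory pathway and of lipid synthesis were higher in HEC together. Of 39 measured genes of the secretory pathway and unfolded protein response, 32 were higher and 2 lower (35 higher and 3 lower adjusted over the list alone), with an adjusted p = 1.08e-12 by camera and an adjusted p = 0.101 with an estimated correlation. Examples were Kdelr3, which retrieves proteins to the endoplasmic reticulum (1.95 ± 0.14), and the signal peptidase subunit Sec11c (1.28 ± 0.15). Of 21 measured genes of cholesterol and fatty acid synthesis, 18 were higher and 1 lower (19 higher and 1 lower adjusted over the list alone), with an adjusted p = 4.72e-11 by camera and an adjusted p = 0.0579 with an estimated correlation. The fatty acid elongase Elovl6 was higher by 2.28 ± 0.12, squalene epoxidase (Sqle) by 2.06 ± 0.11 and the desaturase Scd1 by 1.76 ± 0.14. Other genes among the 10 highest were the serpins Serpina3n (4.53 ± 0.27) and Serpina1c (3.78 ± 0.14), the guidance receptor Robo2 (3.81 ± 0.10), and Oit1 (4.70 ± 0.14), Tc2n (4.32 ± 0.29) and Plxdc2 (3.81 ± 0.09).

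Capillary cells stood higher in arterial, Notch, angiogenic and lipid-uptake genes. Of 19 measured arterial and Notch genes, 18 were lower in HEC and 1 did not pass by limma over all genes tested, and 18 were lower adjusted over the list alone. By camera the list had an adjusted p = 4.08e-23, and an adjusted p = 0.000346 with an estimated correlation. They included the arterial ligand Efnb2 (-3.73 ± 0.07), the Notch target Hey1 (-3.68 ± 0.11), Sema3g (-3.65 ± 0.09) and the gap junction gene Gja5 (-3.12 ± 0.10). Of 20 genes of angiogenesis and VEGF receptors, 17 were lower and 2 higher in HEC (2 higher and 17 lower adjusted over the list alone), with a camera adjusted p = 0.00111 with an estimated correlation. The insulin-like growth factor binding protein Igfbp3 (-4.40 ± 0.09) and the tip cell marker Esm1 (-3.47 ± 0.11) were among them, and the VEGF receptor Kdr was lower by less (-1.02 ± 0.08). Of 16 genes of fatty acid uptake and capillary metabolism, 11 were lower and 4 higher (4 higher and 11 lower adjusted over the list alone). The camera test of these genes gave an adjusted p = 3.56e-06, and an adjusted p = 0.0556 with an estimated correlation. The fatty acid transporter Cd36 (-5.20 ± 0.18), carbonic anhydrase Car4 (-4.95 ± 0.12), the glycerol channel Aqp7 (-4.03 ± 0.13) and Gpihbp1, which holds lipoprotein lipase on capillaries (-3.80 ± 0.10), led that list. Of 19 basement membrane genes 14 were lower and 1 higher in HEC (1 higher and 16 lower adjusted over the list alone). The list gave a camera adjusted p = 4.15e-11, and an adjusted p = 0.0873 with an estimated correlation. The laminin gene Lama4 (-3.62 ± 0.10) and the nidogen gene Nid2 (-3.21 ± 0.06) differed most, beside pericyte and smooth muscle markers that were lower for 9 of 12. Further genes among the 10 lowest were the endothelin receptor Ednrb (-4.68 ± 0.08), Clic5 (-4.08 ± 0.11), the T-cadherin gene Cdh13 (-4.07 ± 0.10) and Rbp7 (-3.88 ± 0.19).

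**Figure D2:**
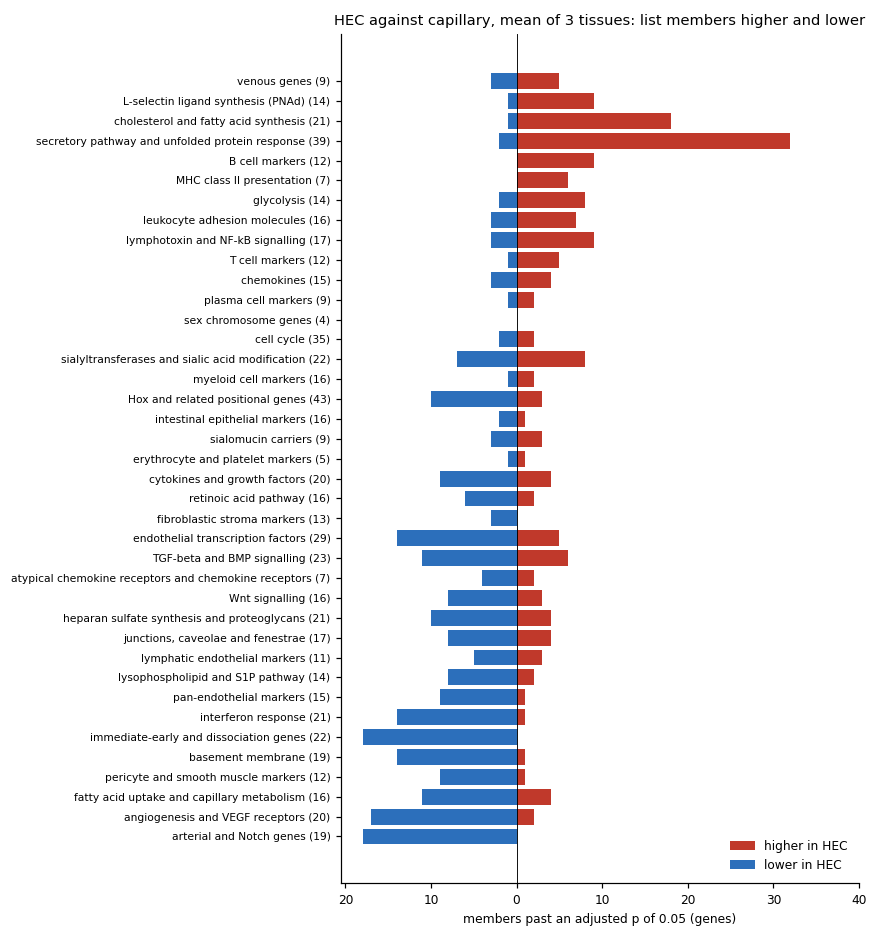
Members of each of the 39 fixed gene lists past an adjusted p of 0.05 in HEC against capillary endothelium as the mean of the 3 tissues, with genes higher in HEC to the right in red and genes lower to the left in blue. The number measured stands in brackets after each list name. All but 1 of the 19 arterial and Notch genes were lower, and 32 of 39 secretory pathway genes were higher.

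Markers of other cells and genes that respond to tissue handling also differed between HEC and capillary sorts. B cell markers were higher in HEC for 9 of 12 measured by limma (10 higher adjusted over the list alone). For this list camera gave an adjusted p = 2.31e-05, and an adjusted p = 0.0893 with an estimated correlation. Spib differed by 1.03 ± 0.07 and the B cell receptor component Cd79b by 0.90 ± 0.12. Genes of MHC class II presentation were higher for 6 of 7 (6 higher and 1 lower adjusted over the list alone), with a camera adjusted p = 0.011 and an adjusted p = 0.156 with an estimated correlation, led by the invariant chain Cd74 (1.30 ± 0.13). Pericyte and smooth muscle markers were lower in HEC for 9 of 12 and higher for 1 (1 higher and 9 lower adjusted over the list alone), with a camera adjusted p = 5.74e-06 and an adjusted p = 0.11 with an estimated correlation, including Rgs5 (-2.71 ± 0.14) and Acta2 (-1.87 ± 0.13). Pan-endothelial markers were lower for 9 of 15 and higher for 1 (1 higher and 9 lower adjusted over the list alone). Tested as a set, these genes had an adjusted p = 0.000386, and an adjusted p = 0.149 with an estimated correlation. The tight junction gene Cldn5 (-2.02 ± 0.18) differed most among these, while Pecam1 differed by -0.06 ± 0.06 and did not pass (adjusted p = 0.503). Immediate-early and dissociation genes were lower in HEC for 18 of 22 by limma (18 lower adjusted over the list alone), with a camera adjusted p = 0.0454 with an estimated correlation, as for Nr4a1 (-1.87 ± 0.07). Interferon response genes were lower for 14 of 21 and higher for 1 (1 higher and 14 lower adjusted over the list alone), with a camera adjusted p = 1.29e-06 and an adjusted p = 0.101 with an estimated correlation, as for Rsad2 (-2.13 ± 0.11).

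In this comparison limma called 6751 of 19938 genes, of which 3588 were higher and 3163 lower in HEC. Of these, 450 were at least 2-fold higher and 461 at least 2-fold lower. Camera called 25 of 39 lists, and 3 with an estimated correlation, which were the arterial and Notch, the angiogenesis and the immediate-early lists. Another split of the arrays within tissue, not the cell types, called 21 lists by camera.

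Within each tissue the same contrast was made to see where HEC and capillary cells differed. In peripheral nodes 2615 genes were higher and 2282 lower in HEC, in mesenteric nodes 1570 and 1457, and in Peyer's patches 1774 and 2107. Across tissues 1010 genes were higher and 961 lower in all 3, against 18.3 and 17.6 for independent lists of those sizes. Madcam1 was higher in HEC by 2.93 ± 0.21 log2 in peripheral nodes, 6.23 ± 0.24 in mesenteric nodes and 5.68 ± 0.23 in Peyer's patches. Chst4 was higher 28.7-fold in peripheral nodes, 31.9-fold in mesenteric nodes and 4.40-fold in Peyer's patches (4.85 ± 0.34 log2 in the first and 2.14 ± 0.36 in the last). PNAd was a gate of the double-positive mesenteric arrays, so the mesenteric fold may partly restate the sort. Without peripheral capillary arrays 1 and 2 the HEC difference of mesenteric minus peripheral nodes was -1.20 for Chst4, so the near-equal folds depend on those arrays. Set directly against peripheral HEC, mesenteric HEC had lower Chst4 (-1.26 ± 0.32, adjusted p = 0.0398 by limma), with the same limit from the PNAd gate. Cd36 was lower in peripheral nodes, mesenteric nodes and Peyer's patches at -5.01 ± 0.30, -5.67 ± 0.34 and -4.92 ± 0.32. The largest differences elsewhere included the thyrotropin receptor Tshr in peripheral nodes (4.52 ± 0.29), the prostaglandin synthase Ptgs2 in Peyer's patches (4.69 ± 0.30) and the secretoglobin Scgb3a1, lower in Peyer's patch HEC (-5.11 ± 0.35). Arterial and Notch genes were lower in HEC for 17, 18 and 18 of 19 by limma (18 in each adjusted over the list alone), with a camera adjusted p = 0.000729, an adjusted p = 0.000104 and an adjusted p = 5.57e-05 with an estimated correlation. Glycam1 was higher by 5.27 ± 0.53 in mesenteric nodes and 6.45 ± 0.50 in Peyer's patches, but by 1.51 ± 0.47 in peripheral nodes (adjusted p = 0.0258). Without peripheral capillary array 3 that difference was 0.66 (adjusted p = 0.149), and its adjusted p was 0.0525 without HEC array 1 and 0.0558 without HEC array 3, 0.139 after quantile normalization and 0.0711 with only the compared groups in the fit. Over 43 genes that marked HEC in the other tissues, capillary arrays 1 and 2 of peripheral nodes lay a median of 0.455 log2 above array 3. Without arrays 1 and 2 Glycam1 differed by 3.22 (adjusted p = 4.04e-05) and the peripheral contrast held 2655 genes, and without mesenteric capillary array 1 the mesenteric contrast held 1791.

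Whether the HEC difference itself depended on tissue was tested as an interaction. It differed between Peyer's patches and peripheral nodes for 808 genes, 336 with a more positive difference in Peyer's patches and 472 with a more negative one. The interaction was 4.93 ± 0.69 for Glycam1, 3.82 ± 0.21 for the apelin receptor Aplnr, 3.69 ± 0.21 for Fjx1 and 3.43 ± 0.22 for the nitric oxide receptor subunit Gucy1a1. It was -4.22 ± 0.47 for Scgb3a1, -3.79 ± 0.26 for Pdlim3 and -2.71 ± 0.50 for Chst4 (adjusted p = 0.00392). Arterial and Notch genes had a more negative HEC difference in Peyer's patches for 10 of 19 measured by limma (13 adjusted over the list alone), with a camera adjusted p = 0.00744 with an estimated correlation. Gja5 (-1.66 ± 0.24) and the kinase gene Bmx (-1.20 ± 0.16) led that list. Cell cycle genes had a more positive difference for 15 of 35 by limma (28 adjusted over the list alone, and 1 more negative). Camera on this list gave an adjusted p = 6.40e-14, and an adjusted p = 0.328 with an estimated correlation. Between mesenteric and peripheral nodes 83 genes had such a difference and between Peyer's patches and mesenteric nodes 150. In the former Madcam1 differed by 3.30 ± 0.32 and Slc7a6 by -2.29 ± 0.20 (-1.50 after quantile normalization), and in the latter the butyrophilin-like gene Btnl9 by 3.60 ± 0.18 and Itih5 by 3.45 ± 0.25. MAdCAM1 was a gating antigen of all mesenteric HEC arrays, so the Madcam1 value may restate the sort and is no finding. The first count was 357 without peripheral capillary arrays 1 and 2, where the Glycam1 interaction was 3.23, 505 without Peyer's patch capillary array 2, and 518 and 2921 without Peyer's patch HEC array 1 or 3. The second was 35 and 38 without mesenteric capillary array 1 or 2, and 52 without mesenteric array 2 of the double-positive gate. It was 46 without peripheral capillary arrays 1 and 2 and 126 after the filter on range, while the third was 73 and 83 without mesenteric capillary array 1 or 2.

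Peyer's patch HEC were compared with peripheral lymph node HEC (3 against 4 arrays). Chst4 was the most reduced named gene in Peyer's patches, at -4.12 ± 0.34 log2 (adjusted p = 5.66e-07), and Madcam1 (3.72 ± 0.21, adjusted p = 6.87e-09) and Fjx1 (3.72 ± 0.15) were the most raised. The labels do not say whether MAdCAM1 or PNAd, to which Chst4 contributes, was used to sort either group, so the differences in Madcam1 and Chst4 cannot be separated from the gates. Also higher were Gucy1a1 (2.99 ± 0.15), Aplnr (2.95 ± 0.14), the leukotriene receptor Cysltr1 (2.69 ± 0.25), the regulator of G protein signalling Rgs16 (2.41 ± 0.15), the sialyltransferase St6gal1 (1.44 ± 0.13), which makes ligands of the B cell lectin CD22, and Nkx2-3 (2.02 ± 0.17), a homeobox factor of gut and spleen vessels. Among the lowest were Itih5 (-3.56 ± 0.16), the amino acid transporter gene Slc7a6 (-3.49 ± 0.13), Ly6e (-3.39 ± 0.12), the urea transporter Slc14a1 (-3.28 ± 0.21), coagulation factor F8 (-3.27 ± 0.27) and the chemokine Pf4 (-3.16 ± 0.21). Lipoprotein lipase (Lpl) was lower too (-3.22 ± 0.53), although peripheral HEC array 1 lay at 0.22 and the other 3 at a mean of 3.32. Of the 14 genes of L-selectin ligand synthesis 4 were lower by limma (6 lower adjusted over the list alone). The camera test gave an adjusted p = 1.05e-05, and an adjusted p = 0.204 with an estimated correlation. Beside Chst4 they included Fut7 (-0.90 ± 0.17) and Chst2 (-0.85 ± 0.13), while Glycam1 differed by 0.09 ± 0.47 (adjusted p = 0.916) and Gcnt1 by -0.13 ± 0.21 (adjusted p = 0.698).

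Genes of MHC class II presentation were lower in Peyer's patch HEC for 6 of 7 measured by limma (6 lower adjusted over the list alone), with a camera adjusted p = 0.0165 with an estimated correlation. H2-Ab1 differed by -2.01 ± 0.16, H2-Aa by -1.79 ± 0.13 and Cd74 by -1.47 ± 0.21. B cell markers were lower for 5 of 12 (6 lower adjusted over the list alone), with a camera adjusted p = 7.27e-06 and an adjusted p = 0.204 with an estimated correlation, led by Fcer2a (-1.24 ± 0.17) and Ms4a1 (-1.06 ± 0.17). T cell markers were lower for 4 of 12 (1 higher and 4 lower adjusted over the list alone), with a camera adjusted p = 0.198 and an adjusted p = 0.723 with an estimated correlation. Of 43 Hox and related positional genes 5 were higher and 2 lower (6 higher and 2 lower adjusted over the list alone). By camera the list had an adjusted p = 0.00235, and an adjusted p = 0.605 with an estimated correlation. The homeobox gene Meis2 was higher by 2.42 ± 0.17 and Hoxd8 lower at -1.09 ± 0.17. Cell cycle genes were higher for 7 of 35 by limma (20 higher adjusted over the list alone), with a camera adjusted p = 1.64e-07 and an adjusted p = 0.499 with an estimated correlation, and Rrm2 led them (0.80 ± 0.16). Genes of cholesterol and fatty acid synthesis were higher for 6 of 21 (13 adjusted over the list alone). The camera test of these genes gave an adjusted p = 1.82e-06, and an adjusted p = 0.281 with an estimated correlation. Their largest member was Scd1 (1.08 ± 0.23). Intestinal epithelial markers were higher for 9 of 16 by limma (10 higher adjusted over the list alone). The list gave a camera adjusted p = 1.18e-07, and an adjusted p = 0.307 with an estimated correlation. They included the galectin Lgals4 (1.22 ± 0.24) and the keratin Krt19 (1.08 ± 0.18), and 24 further epithelial genes had a median difference of 0.565. Pan-endothelial markers were lower for 6 of 15 (9 lower adjusted over the list alone). For this list camera gave an adjusted p = 4.07e-05, and an adjusted p = 0.281 with an estimated correlation. Agr2, a protein disulfide isomerase of mucus-secreting cells, was among the 10 highest genes (2.29 ± 0.26).

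For Peyer's patch against peripheral HEC limma called 1326 genes, 431 higher and 895 lower, and 10 lists by camera, of which 1, MHC class II presentation, held with an estimated correlation. Without Peyer's patch HEC array 1, 2 or 3 the count of genes was 712, 790 or 5300, without peripheral HEC array 4 it was 858, and with these 7 arrays alone in the fit it was 743. Another split of the same 7 arrays, not the tissues, called 2129 genes. It exchanged Peyer's patch array 3 and peripheral array 2, and the next highest other split called 151.

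**Figure D3:**
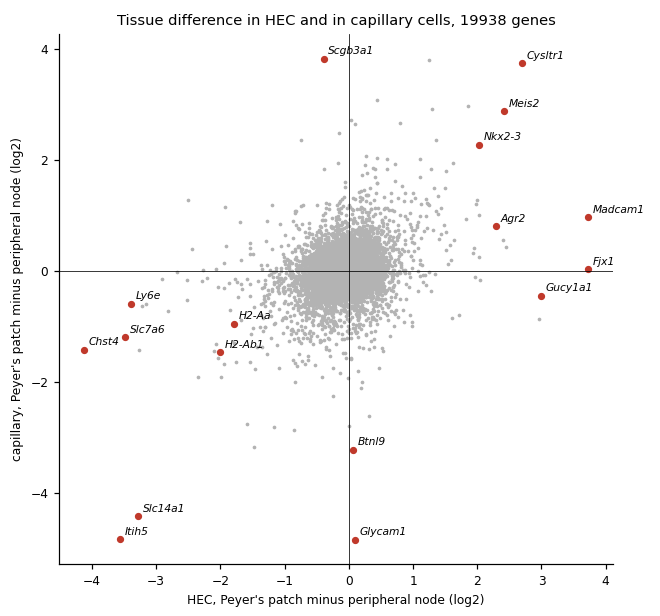
Peyer's patch minus peripheral node difference (log2) in HEC on the horizontal axis and in capillary cells on the vertical axis, with a point for each of 19938 genes and named genes in red. Madcam1, Fjx1 and Gucy1a1 lay to the right, Scgb3a1 at the top, and Chst4, Itih5 and Slc14a1 at the lower left. Glycam1 lay at 0.09 in HEC and -4.84 in capillary cells.

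Mesenteric HEC were set against HEC of peripheral nodes and of Peyer's patches, as the mean of their gates. Against peripheral HEC the mesenteric cells were higher in the heat shock gene Hspa1a (2.60 ± 0.21), the prostaglandin transporter Slco2a1 (1.69 ± 0.21), Fjx1 (1.63 ± 0.14) and Nkx2-3 (1.53 ± 0.16), and lower in Slc7a6 (-3.50 ± 0.12), Itih5 (-3.23 ± 0.15), F8 (-2.60 ± 0.25) and Pf4 (-2.24 ± 0.20). Hspa1a is an immediate-early and dissociation gene, and 3 of these 22 were higher and 1 lower (4 higher and 1 lower adjusted over the list alone). Their camera adjusted p was 0.0106, and 0.438 with an estimated correlation. A part of tissue handling in the Hspa1a difference was not tested. Madcam1, the gene of a gating antigen, was higher by 3.50 ± 0.20. Chst4 was lower (-1.26 ± 0.32, adjusted p = 0.0398). Of 14 measured genes of L-selectin ligand synthesis 2 were lower by limma (2 lower adjusted over the list alone). That list had a camera adjusted p = 0.000934, and an adjusted p = 0.429 with an estimated correlation. Of 43 Hox and related positional genes 7 were higher and 2 lower (11 higher and 3 lower adjusted over the list alone), with a camera adjusted p = 7.43e-06 and an adjusted p = 0.429 with an estimated correlation, including Meis2 (1.64 ± 0.15). Against mesenteric HEC, Peyer's patch HEC were higher in Agr2 (2.28 ± 0.26), Ptgs2 (2.13 ± 0.28) and Fjx1 (2.09 ± 0.15) and lower in Chst4 (-2.86 ± 0.34), Ly6e (-2.29 ± 0.12) and the iron hormone gene Hamp (-2.38 ± 0.25), while Madcam1 differed by 0.23 ± 0.21 (adjusted p = 0.711). Chst4 contributes to PNAd, a gate of the double-positive mesenteric arrays, so neither of its differences from mesenteric HEC can be separated from the sort. MHC class II genes were lower in Peyer's patches for 4 of 7 by limma (5 lower adjusted over the list alone), with a camera adjusted p = 0.0137 with an estimated correlation, as for H2-Ab1 (-1.43 ± 0.16), and B cell markers had a median difference of -0.18 (camera adjusted p = 0.000528, and an adjusted p = 0.321 with an estimated correlation). Intestinal epithelial markers were higher there for 4 of 16 (8 higher adjusted over the list alone). Tested as a set, these genes had an adjusted p = 6.53e-11, and an adjusted p = 0.26 with an estimated correlation. Limma called 537 genes between mesenteric and peripheral HEC, 144 higher and 393 lower, and 239 between Peyer's patch and mesenteric HEC, 111 higher and 128 lower. The first count was 285 without double-positive array 2 and 324 without MAdCAM1-positive array 4. The second was 123 and 130 without these, 98 and 946 without Peyer's patch HEC array 1 or 3, 80 with only the compared groups in the fit, and 374 after the filter on range.

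Capillary endothelium was compared between the tissues as well. In Peyer's patches against peripheral nodes (3 against 3 arrays) the secretoglobin Scgb3a1 (3.83 ± 0.35), the chloride channel regulator gene Clca3a1 (3.81 ± 0.28), Cysltr1 (3.74 ± 0.26) and the retinoic acid-degrading enzyme Cyp26b1 (3.07 ± 0.18) were highest, and Nkx2-3 was higher by 2.27 ± 0.18. Itih5 (-4.84 ± 0.17), Slc14a1 (-4.42 ± 0.22), Btnl9 (-3.22 ± 0.12) and carbonic anhydrase Car2 (-2.86 ± 0.21) were lower, as was Glycam1 (-4.84 ± 0.50). Arterial and Notch genes were higher in Peyer's patch capillaries for 8 of 19 and lower for 1 (11 higher and 1 lower adjusted over the list alone), with a camera adjusted p = 0.00738 with an estimated correlation, and Gja5 was higher by 1.60 ± 0.18. MHC class II genes were lower for 5 of 7 by limma (6 lower adjusted over the list alone), with a camera adjusted p = 0.0137 with an estimated correlation, as for Cd74 (-1.76 ± 0.22) and H2-Ab1 (-1.46 ± 0.17). Myeloid cell markers were lower for 3 of 16 (5 adjusted over the list alone). Camera on this list gave an adjusted p = 5.16e-05, and an adjusted p = 0.191 with an estimated correlation. Immediate-early and dissociation genes were higher for 7 of 22 and lower for 1 (8 higher and 1 lower adjusted over the list alone), with a camera adjusted p = 2.61e-06 and an adjusted p = 0.191 with an estimated correlation, led by Socs3 (1.45 ± 0.17). Cell cycle genes were lower for 3 of 35 by limma (1 higher and 20 lower adjusted over the list alone). The camera test gave an adjusted p = 3.69e-09, and an adjusted p = 0.207 with an estimated correlation. Pericyte and smooth muscle markers were lower for 4 of 12 and higher for 1 (1 higher and 7 lower adjusted over the list alone), with a camera adjusted p = 2.79e-05 and an adjusted p = 0.191 with an estimated correlation, led by Acta2 (-1.39 ± 0.23). Intestinal epithelial markers were higher for 4 of 16 by limma (10 higher adjusted over the list alone), with a camera adjusted p = 4.03e-08 and an adjusted p = 0.191 with an estimated correlation, and the 24 further epithelial genes had a median of 0.343. The 14 genes of L-selectin ligand synthesis were lower for 7 by limma (8 lower adjusted over the list alone). By camera the list had an adjusted p = 7.14e-05, and an adjusted p = 0.191 with an estimated correlation. The venous genes Ackr1 (-1.11 ± 0.19) and Nr2f2 (-0.72 ± 0.15) were also lower, among 3 of 9 venous genes called lower (3 adjusted over the list alone), with an adjusted p = 0.196 with an estimated correlation. Of 43 genes that marked HEC in the other tissues, Glycam1, Chst4 and Oit1 left out, 40 lay higher on peripheral capillary arrays 1 and 2 than on array 3 (median 0.455). HEC RNA in the peripheral capillary sort may thus contribute to the lower L-selectin ligand and venous genes, which was not tested. Limma called 925 genes, 478 higher and 447 lower, of which 101 and 147 had the same direction in HEC, against 10.3 and 20.1 for independent lists. Another 24 genes were lower in capillary cells and higher in HEC, and 27 the reverse, against 9.66 and 21.5. Across all genes, which are not independent replicates, the capillary and HEC differences had a Pearson r of 0.194 and a Spearman rho of -0.0333. Without peripheral capillary arrays 1 and 2 the count was 354, Glycam1 was at -3.13, and Acta2, Ackr1 and Nr2f2 did not pass (adjusted p = 0.167, 0.0618 and 0.455), with the 1 array left. Nr2f2 did not pass without array 2 alone either (adjusted p = 0.0584).

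Mesenteric capillaries (2 arrays) differed from those of peripheral nodes in 58 genes, 24 higher and 34 lower. Leaving out either mesenteric array leaves a lone one, which is assumed to vary like the other groups. Scgb3a1 (3.11 ± 0.39) and Meis2 (1.71 ± 0.20) were higher, and Slc14a1 (-2.73 ± 0.25) and the interferon-inducible chemokine Cxcl9 (-1.56 ± 0.19) lower. Glycam1 was at -3.69 ± 0.56 (adjusted p = 0.00609), with an adjusted p = 0.0571 without mesenteric capillary array 1 and an adjusted p = 0.132 without array 2. Immediate-early and dissociation genes did not pass for 22 of 22 by limma over all genes tested, while 10 were higher in mesenteric capillaries adjusted over the list alone (median 0.33), with a camera adjusted p = 0.0228 with an estimated correlation. Genes of fatty acid uptake and capillary metabolism were higher for 1 of 16 (10 adjusted over the list alone), with a camera adjusted p = 0.0228 with an estimated correlation. In Peyer's patches against mesenteric nodes Clca3a1 (3.32 ± 0.31), Cysltr1 (3.27 ± 0.30), Cyp26b1 (2.87 ± 0.20) and Myof (2.82 ± 0.16) were higher, and Itih5 (-3.77 ± 0.19), Btnl9 (-3.63 ± 0.13), Angptl4 (-3.06 ± 0.39), an inhibitor of lipoprotein lipase, and Sema3c (-2.60 ± 0.17) lower. MHC class II genes were lower for 3 of 7 by limma (4 lower adjusted over the list alone), with a camera adjusted p = 0.0409 with an estimated correlation. Myeloid cell markers were lower for 2 of 16 (2 adjusted over the list alone), with a camera adjusted p = 0.0299 and an adjusted p = 0.594 with an estimated correlation. That comparison held 370 genes, 204 higher and 166 lower. The count of 58 was 15 and 23 without mesenteric capillary array 1 or 2, 32 without peripheral capillary array 1, 4 without peripheral capillary arrays 1 and 2 (adjusted p = 0.0605 for Scgb3a1, 0.181 for Cxcl9 and 0.266 for Glycam1), 124 (65 higher, 59 lower) after quantile normalization, and 0 by limma with only the compared groups in the fit (1011 at an unadjusted p under 0.05). The count of 370 was 199 and 167 without mesenteric capillary array 1 or 2, and 224 with only the compared groups.

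The 2 mesenteric HEC gates were compared with 2 arrays each. Leaving out an array leaves a lone one in its gate, which is assumed to vary like the other groups. Limma called 0 genes higher and 4 lower in the MAdCAM1 and PNAd double-positive cells, with 335 genes at an unadjusted p under 0.05. They were Myof (-1.65 ± 0.17), Cytl1 (-1.39 ± 0.14), the fibulin gene Fbln2 (-1.29 ± 0.16) and the neurokinin receptor Tacr1 (-1.17 ± 0.17). Chst4, whose enzyme makes part of the PNAd epitope used as a gate, differed by 1.49 ± 0.45 (adjusted p = 1). This SE rests on a spread shared by all 7 groups, to which peripheral capillary arrays contribute. The adjusted p therefore does not show that the gates were alike in Chst4. Without peripheral capillary array 3, or without arrays 1 and 2 of that group, Chst4 passed (adjusted p = 0.00453 and 0.00113). The count was 17 without MAdCAM1-positive array 4 and 0 by limma with only the compared groups in the fit (572 at an unadjusted p under 0.05). Fbln2 did not pass without double-positive array 2 (adjusted p = 0.0838), nor Tacr1 without double-positive array 1 (adjusted p = 0.515) or MAdCAM1-positive array 4 (adjusted p = 0.167).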

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

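The test of a single share of HEC RNA for Glycam1 and both tests on the spread of Peyer's patch HEC arrays were chosen only after the result was seen, as was the fit without peripheral capillary arrays 1 and 2. In the 4 peripheral HEC arrays, the group of that size, a gap of one array to the nearest of the others was set against the range of the group. It took more than the critical share of the range for 9 of 154 genes, where chance gives about 1 in 20, or 7.7. The shares were 0.837 for Btg2 and 0.843 for Csf3 on array 3, 0.915 for Egr3 and 0.896 for Ms4a1 on array 2, 0.865 for Fmo2, 0.876 for Lpl and 0.877 for Slco2a1 on array 1, and 0.867 for Itih5 and 0.895 for Oit1 on array 4. Lpl had the widest gap, at 0.22 on array 1 against 3.32 ± 0.22 (SD, n = 3) on the others.

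The HEC difference itself varied with tissue for 808 genes between Peyer's patches and peripheral nodes, 83 between mesenteric and peripheral nodes, and 150 between Peyer's patches and mesenteric nodes, by the interaction terms. For the first, 1 of 100 drawn splits of tissue within cell type, the real one, gave as many genes, a share under 0.05. The structure of the samples gave a count near the real one, with 655 as the highest other. For the HEC part, Peyer's patch against peripheral HEC, chance could not be excluded. The drawn splits therefore do not settle whether chance is excluded for this interaction. Its named log2 differences were Glycam1 4.93, Aplnr 3.82, Fjx1 3.69, Gucy1a1 3.43, Btnl9 3.28, Madcam1 2.75, Ackr1 1.23 and Nr2f2 1.17 on the positive side. On the negative side they were Scgb3a1 -4.22, Pdlim3 -3.79, Plat -3.12, Fmo2 -3.08, Chrm3 -2.84, Chst4 -2.71, Gja5 -1.66, Esm1 -1.26, Bmx -1.20, Hey2 -1.09 and Gja4 -1.03. For mesenteric against peripheral nodes they were Glycam1 3.76, Madcam1 3.30 (the gene of a gating antigen, so no finding), Lrrc55 2.10, Lgals1 1.60, Cd109 1.56, Scgb3a1 -2.80, Pdlim3 -2.42, Slc7a6 -2.29, F8 -2.25 and Itih5 -2.17. For Peyer's patches against mesenteric nodes they were Btnl9 3.60, Itih5 3.45, Angptl4 3.41, Sema3c 2.84, Rbp7 2.64, Chst4 -2.86, Plat -2.64, Cyp26b1 -2.58, Pcx -2.52, Clca3a1 -2.33, Esm1 -1.27 and Gja5 -1.21. Outside the named genes, 1330 of 7067 probe sets without a single gene name passed the threshold in HEC against capillary cells, 577 higher and 753 lower.

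Other splits of the same arrays were counted for the remaining comparisons. For HEC against capillary cells as the mean of tissues 1 of 100 drawn splits, the real one, gave as many genes (6751, highest other 37), so a chance split can be excluded for the genes. For lists 1 of 100 gave as many (25, highest other 21). The make-up of the split with 21 lists was not examined, and it may keep most HEC arrays apart from most capillary arrays. How much of the list count can arise without the cell types is thus unknown, and chance is not excluded for the list calls. In peripheral nodes 1 of 35 splits, the real one, gave 4897 genes (highest other 2496, with HEC array 2 moved to the capillary side). With both mesenteric gates as one group, 1 of 35 splits gave 541 genes against peripheral HEC (highest other 1) and 1 of 35 gave 236 against Peyer's patch HEC (highest other 11). In each the real split ranked first, the smallest share that 35 splits allow. Replicate arrays may be technical, so this can exclude a chance split of the arrays, but not chance between samples. In Peyer's patches (1 of 10 splits, real 3881, highest other 24) and for capillary cells of Peyer's patches against peripheral nodes (1 of 10, real 925, highest other 0) there are too few splits for a share under 0.05. For Peyer's patch against peripheral HEC chance could not be excluded. There 2 of 35 splits gave 1326 or more genes, and 8 of 35 gave 10 or more lists. The highest other counts were 2129 genes, with Peyer's patch arrays 1 and 2 and peripheral array 2 on one side, and 16 lists. The second highest other count of genes was 151.

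Glycam1 lay near its HEC level on peripheral capillary arrays 1 and 2. RNA of HEC in that sort is a candidate explanation, since 40 of 43 genes that marked HEC in the other tissues, Glycam1, Chst4 and Oit1 left out, lay higher on these arrays than on array 3, with a median of 0.455 log2 (quartiles 0.247 and 0.584), against -0.02 for 49 capillary genes. Glycam1 itself was 2.56 above array 3. A single share of HEC RNA with signals in proportion to RNA is argued against as the whole cause, since the gap from HEC to these arrays was 0.657 for Glycam1, below the smallest of the set (1.29, median 3.02). A saturated Glycam1 signal and expression in peripheral capillary cells stay open and were not tested.

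Intestinal epithelial transcripts were higher in both Peyer's patch sorts. RNA of intestinal epithelium may have entered them, since 24 measured epithelial genes outside the fixed lists had a median difference from peripheral nodes of 0.565 log2 in HEC and 0.343 in capillary cells, above 0 in 22 and 24 of them, with 8 and 2 past the threshold upward and 1 in HEC past it downward. The labels give no gate for these sorts that would remove epithelium, and expression of the genes in gut endothelium stays open as untested.

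Peyer's patch HEC arrays 2 and 3 lay further apart than any other replicate pair. An axis of RNA or array quality shared with other groups is a candidate explanation, since their difference correlated across genes, which are not independent replicates, at a size of 0.614 with the first within-group component of peripheral capillary cells and 0.509 with that of peripheral HEC. The size was 0.418 for Peyer's patch capillary cells, 0.341 for double-positive mesenteric HEC, and only 0.121 and 0.119 for MAdCAM1-positive mesenteric HEC and mesenteric capillary cells. For RNA of another cell type the largest median difference of a marker list was 0.492, for T cell markers (quartiles 0.308 and 0.541), which lies too near the bound of 0.5 set for the test to decide. A difference between the mice or sorts behind the arrays was not tested. As the same arrays decide the count against peripheral HEC, that count may carry this axis as well as the tissue.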

How the results depend on the processing

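The filter on range, the robust prior, the most variable probe set, the fits without peripheral capillary arrays 1 and 2 or without array 1 of both peripheral groups, and the pairing of mesenteric HEC arrays were chosen only after the result was seen. Over all alternatives and omissions 17025 values of named genes kept their direction and side of the threshold, 425 lost the call, 69 gained one and 2 reversed. Many of these values could hardly change, so the tally is no measure of robustness. Each other choice of probe set kept 567 of 567 values, and none of the 87 largest or fixed genes had more than 1 probe set. Many omissions concerned a group outside the contrast and acted only through the shared spread. The reversed values were B3gnt3 between Peyer's patch and peripheral HEC, 0.19 with array weights, and the Chst4 interaction of mesenteric and peripheral nodes, -1.20 without peripheral capillary arrays 1 and 2. The cause was not tested for any count below unless named.

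The estimate of array quality weights stopped before it converged and gave Peyer's patch HEC array 1 a weight of 41.6 against at most 2.30 for the others, so these counts cannot be relied on. They were 10439 for HEC against capillary cells in Peyer's patches, 11209, 1199 and 7138 for HEC of Peyer's patches against peripheral, mesenteric against peripheral and Peyer's patches against mesenteric nodes, 1516, 91 and 790 for capillary cells in the same order, 6443, 155 and 1703 for the interactions, and 10 for the gates. With only the compared groups, which leaves fewer arrays, HEC of Peyer's patches gave 743 genes against peripheral and 80 against mesenteric nodes, capillary cells 0 for mesenteric against peripheral nodes and 224 for Peyer's patches against mesenteric nodes, and the gates 0, where limma gave 1011 and 572 genes at an unadjusted p under 0.05 for the counts of 0. Without peripheral capillary arrays 1 and 2, where the lone array is assumed to vary like the other groups, the counts were 2655 (HEC against capillary cells of peripheral nodes), 354 and 4 (capillary cells of Peyer's patches and mesenteric nodes against peripheral nodes), and 357 and 46 (the interactions with peripheral nodes). Without array 1 of both peripheral groups, mesenteric against peripheral capillary cells gave 27. The filter on range, with fewer genes tested, gave 374 for Peyer's patch against mesenteric HEC and 126 for the interaction of mesenteric and peripheral nodes. Quantile normalization gave 124 for mesenteric against peripheral capillary cells (65 higher, 59 lower, against 24 and 34) and split the interaction of mesenteric and peripheral nodes into 40 higher and 49 lower, against 29 and 54. With an estimated correlation 3 and 1 lists passed, against 25 and 10. No shift of the median of all genes passed 0.1 under either scaling.

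The replicate numbers did not meet the bar set for pairing, a correlation over 0.1 in every pair. Of 41 pairs with the same number 17 correlated over 0.1 (from -0.43 to 0.56), and 4 of 19 arrays correlated best with their own number. HEC and capillary arrays 1, 2 and 3 correlated at 0.0839, 0.376 and -0.196 in peripheral nodes and at -0.110, 0.0650 and -0.397 in Peyer's patches, and mesenteric capillary and double-positive HEC arrays at 0.440. Array 1 of both peripheral groups had low Y-linked genes. Xist was low on array 2 of mesenteric capillary cells and of double-positive HEC, and also on MAdCAM1-positive HEC array 4. A shared origin of some arrays, with the same number or across the mesenteric HEC gates, therefore stays open. A block on the number does not cover the latter. Pairing mesenteric HEC arrays by correlation kept 561 of 567 values of named genes, while 4 gained the call and 2 lost it. With the number as a replicate block, Peyer's patch against mesenteric HEC gave 153 genes and the gates 2, and no other count moved by over 1.5 times.

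Leaving out each array gave 5827 to 7362 genes for HEC against capillary cells as the mean of tissues, and 3272 to 5842, 1791 to 3428 and 2943 to 4441 in peripheral nodes, mesenteric nodes and Peyer's patches. For HEC it gave 712 to 5300 (Peyer's patches against peripheral nodes), 285 to 665 (mesenteric against peripheral) and 98 to 946 (Peyer's patches against mesenteric). For capillary cells it gave 648 to 1041, 15 to 68 and 167 to 429 in that order. The interactions ranged over 505 to 2921, 35 to 89 and 73 to 220, the gates over 3 to 17, and the lists over 24 to 26 and 8 to 12. In groups of 2 arrays an omission left a lone array, which is assumed to vary like the other groups. The dim filter and the intensity trend were not run, and without signal levels the depth of a low call is unknown.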

Other observations

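All genes of this part but Robo2 were chosen after their values were seen, and no test was run on them beyond the model and its alternatives, under all of which the 7 called ones kept their side of the threshold. In HEC against capillary cells as the mean of tissues, enzymes that set oxysterol levels differed unevenly. Cholesterol hydroxylase Ch25h was higher in HEC by 3.24 ± 0.14 log2 (adjusted p = 4.73e-12), the sterol hydroxylase Cyp27a1 by 2.89 ± 0.13 (adjusted p = 1.08e-11) and Hsd3b7, which degrades oxysterol ligands of the lymphocyte receptor Gpr183, by 1.41 ± 0.11 (adjusted p = 8.19e-09). Cyp7b1, the other hydroxylase needed to make those ligands, differed by -0.03 ± 0.10 (adjusted p = 0.886). Complement genes went both ways, with C1s1 higher by 3.70 ± 0.20 and factor B (Cfb) by 3.53 ± 0.09, and Serping1, the inhibitor of C1 proteases, lower at -1.39 ± 0.17. The guidance receptor Robo1 was higher by 2.67 ± 0.07, beside Robo2 (3.81 ± 0.10).

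On array 1 of peripheral capillary cells the Y-linked genes Eif2s3y and Uty lay at -1.61 and -1.65 log2, and on array 1 of peripheral HEC at -1.99 and -1.61. Uty lay no lower than -0.65 on the other 17 arrays, and Eif2s3y no lower than -1.02, its value on Peyer's patch HEC array 2. Xist, another sex chromosome gene, lay at -1.07 on mesenteric capillary array 2, -0.61 on double-positive HEC array 2 and -0.73 on MAdCAM1-positive HEC array 4. On all other arrays Xist lay no lower than -0.12, its value on mesenteric capillary array 1. The cause of these values was not tested.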
